A study of Mus musculus with 6 samples.

How the data were processed

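RNA of 6 macrophage samples, 2 each at 0, 0.1 and 10 ng/ml LPS for 4 h, was isolated with a Qiagen kit, labelled with biotin and read on Illumina mouse bead arrays of 25697 probes, 1 array per sample. The cells had been preincubated for at least 2 h in a salt buffer with 2% serum before LPS was added. Per the file headers, the deposited files per array give the mean bead signal of each probe as an intensity, a detection p-value, the standard error of the bead signals and the number of beads averaged. The authors' processing notes name GenomeStudio 2011.1 without its settings. A combined deposited file held the same intensity and detection p values, with a largest difference of 0. The authors' series value table held 17187 probes as log2 values with identical quantiles in every column (median 7.43), within 0.105 of the quantile-normalized log2 of the intensities. None of the 8510 probes missing from it was detected at p under 0.05 on 2 arrays.

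Detection p-values lay in steps of 1 over 798. At a detection p under 0.01, 8945 and 10520 probes were detected on the untreated arrays, 9116 and 10446 on the low-LPS arrays and 8026 and 8554 on the high-LPS arrays. The bead standard error was 2.66% to 2.86% of the signal, and the 6 arrays limit the precision.

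Intensities were background-corrected by normexp with the detection p-values (offset 16), quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Probes detected at p under 0.01 on at least 2 of the 6 arrays were kept, 10458 in all. The annotation table covered 16120 probes and gave 1 symbol to each, while 9577 probes had no entry and stayed unnamed. Symbols were matched by Entrez number for 16110 probes and by sequence accession for 5, and 5 were not matched. For the 1953 genes with more than 1 passing probe, the probe with the highest mean signal stood for the gene. Of 297 called genes with other passing probes, 10 had another probe with the opposite sign. In all 7767 features were tested, and no genome positions were used.

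A linear model with 1 mean per group was fitted to all 6 arrays with limma and eBayes (3 residual and 2.277 prior degrees of freedom), with contrasts of low with zero, high with zero and high with low LPS. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Where a gene was undetected on 1 or both arrays of the lower group, those arrays were set to the lowest detected signal of the array and the fold is given as a lower bound. Of 31 gene lists with 592 members, fixed before the data were examined, 467 members had a named probe and 404 were measured. The 21 lists of the study's own genes, of responses and of RNA quality and stress with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The Ikaros list had too few measured members for a list test, and 9 lists of markers of other cell types were counted without one.

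Named genes followed a rule fixed before the data were examined. It took the 12 largest rises and 8 largest falls against zero LPS, and the 10 largest of each between the doses, among called genes whose arrays did not overlap between groups. It added every measured NF-kB, IkB and Ikaros gene, Tnfaip3, and up to 4 members of each other list with the smallest p. Since no gene was called at low LPS, the rule was applied there to the slide-block fit, a choice made after seeing the data.

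Deviations of the replicates from their group means correlated across genes with r = 0.767 between zero and low, 0.649 between zero and high and 0.634 between low and high LPS, so the replicate numbers were treated as a pairing in blocked fits. With only 2 numbers per group the basis for this is thin, and genes are not independent replicates. The 3 replicate 1 arrays lay on 1 slide, replicate 2 of the untreated and low-LPS groups on another, and replicate 2 of the high-LPS group alone on the last. Comparisons with high LPS within a slide therefore rest on replicate 1. Blocked fits had 2 (replicate) and 1 (slide) residual degrees of freedom, and the random replicate effect had a correlation of 0.548.

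Alternatives covered the background offset (50), no background correction, cyclic loess, median scaling, the authors' values, the detection filter, the probe per gene, the threshold, the variance model, array weights, the arrays in the fit, the blocks and leaving out each array. Scaling on the probes detected on all 6 arrays was added after seeing the data. The pipeline, with the fit without a block, was tested on simulated data of 7767 genes in 20 simulations, where 22%, 66.2%, 81.4% and 88.9% of genes changed 2-, 4-, 8- and 16-fold were recovered and 5.28% of calls were false. In these simulations camera called the shifted list in 20 and an unshifted list in 1. Items withheld from the files were not analysed here.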

Results

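Mouse bone-marrow-derived macrophages, phagocytic cells grown from C57BL/6 marrow precursors with the growth factor M-CSF, were profiled after 4 h without lipopolysaccharide (LPS) and after 4 h with LPS at 0.1 ng/ml (low) or 10 ng/ml (high). LPS is a component of the outer membrane of Gram-negative bacteria and activates Toll-like receptor 4 (TLR4). Each of the 3 groups held 2 samples, numbered replicate 1 and replicate 2 in the labels, and each sample was read on 1 bead array of 25697 probes. Between 8026 and 10520 probes were detected per array, and the median probe signal averaged 38 to 40 beads. After filtering, 7767 features were tested, made up of 7176 named genes and 591 probes without a gene name. The labels do not say whether the 2 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical, and the 6 arrays limit the precision.

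The first principal component of the normalized values held 62.4% of the variance and placed the high-LPS arrays at 52.6 and 52.8, the low-LPS arrays at -6.96 and -26.4 and the untreated arrays at -26.6 and -45.4 (replicates 1 and 2). The second component held 25.7% and separated the replicate numbers. In a limma fit with group and replicate terms, 744 genes were higher in replicate 2 and 599 were higher in replicate 1. Ctse, which encodes the protease cathepsin E, was undetected on the 3 replicate 1 arrays and at least 31.5-fold higher in replicate 2 (3 arrays per replicate number, limma adjusted p = 0.000285). The leukocyte protein gene Lsp1 was 8.29-fold higher in replicate 2 (log2 difference 3.05 ± 0.13 SE). Replicate 1 had the higher signal of Apoe (apolipoprotein E, log2 difference -3.29 ± 0.15), of the scavenger receptor gene Marco (-3.44 ± 0.21) and of Nr1h3, which encodes the nuclear receptor LXR alpha (-3.11 ± 0.20). These genes were picked for their size after their values were seen. All 3 replicate 1 arrays lay on 1 slide and the replicate 2 arrays lay on 2 other slides, so slide and replicate number cannot be told apart for these genes.

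**Figure D1:**
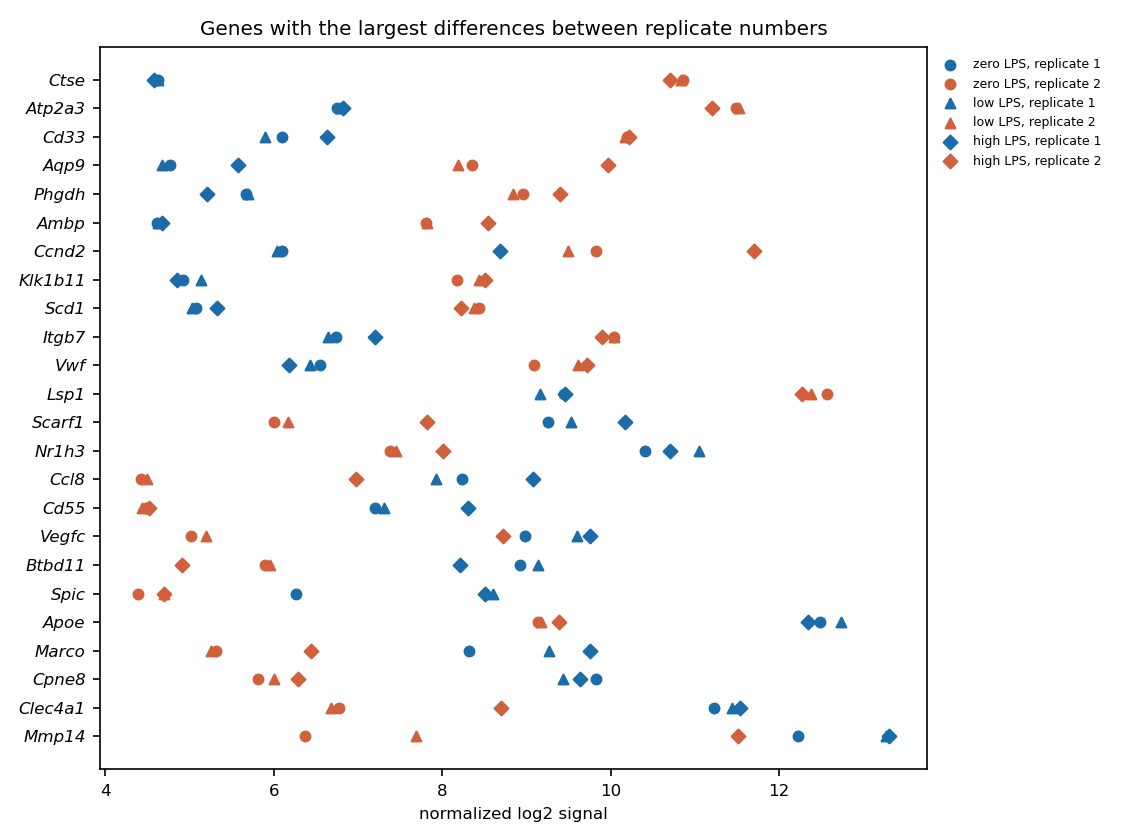
Normalized log2 signal (horizontal axis) of the 12 named genes with the largest excess in replicate 2 and the 12 with the largest excess in replicate 1, 1 row per gene, with each point an array, colour for the replicate number and shape for the LPS group. Ctse lies between 4.58 and 4.62, below detection, on the replicate 1 arrays and between 10.7 and 10.9 on the replicate 2 arrays.

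The comparison of high LPS with no LPS asked how the transcripts of these cells changed at the higher dose. Among the largest rises, Edn1, encoding the vasoactive peptide endothelin-1, was not detected without LPS and was at least 103-fold higher with it (log2 change 7.46 ± 0.27 SE, n = 2 arrays per group, limma adjusted p = 0.00255). The interleukin genes Il1b, Il1a and Il27 were likewise undetected without LPS and at least 472-fold, 167-fold and 85.6-fold higher. The largest falls were in Cdca7, a gene linked to cell division, at least 22.5-fold lower (log2 change -4.91 ± 0.19, adjusted p = 0.00255), and in Sesn1, a stress-response gene, at least 29.6-fold lower. Sesn1 was detected on 1 of 2 high-LPS arrays, and its other probe had a log2 change of -2.11 against -4.89. Other named rises were Cd69 (195-fold), Cxcl10 (118-fold), Cxcl9 (at least 90.4-fold, detected on 1 of 2 untreated arrays), Cxcl2 (109-fold), Socs3 (104-fold), Ccl5 (94.1-fold), and Cxcl1 and Gbp5, which were at least 98.3-fold and 51.7-fold higher. Fam78a, Gpr183, Rab3il1, Cnr2 and Lbh fell to below detection, by at least 11.5-fold, 7.66-fold, 7.41-fold, 8-fold and 12.1-fold (for Lbh, another probe had a log2 change of -1.76 against -3.91), and Tmem86a fell 14.7-fold.

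Of the NF-kB subunit genes, 3 of 4 measured rose. Rel, detected on 1 of 2 untreated arrays, rose at least 6.76-fold (log2 change 2.99 ± 0.49, adjusted p = 0.0217), Nfkb2 rose 7.18-fold (2.84 ± 0.55, adjusted p = 0.0308) and Rela, which encodes the main activating subunit, rose 1.83-fold (0.87 ± 0.17, adjusted p = 0.0323). Relb had a log2 change of 2.43 ± 0.67 with an adjusted p of 0.0697, and 0.0126 with the replicate number as a block. Nfkb1 was not analysed here. Of the genes of IkB proteins, which bind NF-kB and mostly restrain it, 5 of 6 rose. Nfkbiz rose 39-fold (5.29 ± 1.09, adjusted p = 0.0365), Nfkbie 9.39-fold, Nfkbia 6.36-fold, Nfkbib 4.84-fold and Bcl3 4.57-fold, while Nfkbid had a log2 change of 1.28 ± 0.79 (adjusted p = 0.321). Tnfaip3, encoding the deubiquitinating inhibitor A20, had a log2 change of 3.75 ± 0.94 with an adjusted p of 0.0569, and 0.033 with the replicate block. Ikzf1, encoding the transcription factor Ikaros, rose 7.38-fold (2.88 ± 0.22, adjusted p = 0.0063), and the related Ikzf5 had a log2 change of 0.32 ± 0.22 (adjusted p = 0.361).

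Interferon-stimulated genes were the list with the most rises, 26 of 36 measured members and 34 when adjusted over the list alone, with a median log2 change of 2.95. Its camera adjusted p was 6.39e-22, and the adjusted p = 0.207 with an estimated correlation. The median was 2.13 within replicate 1, whose arrays shared a slide, and 3.44 within replicate 2, whose high-LPS array was alone on its slide. The untreated arrays differed too, with a median of -1.01 for replicate 2 minus replicate 1 over this list. Isg20 and Ifi47 were undetected without LPS and at least 14.4-fold and 8.78-fold higher. Of the cytokine genes, 10 of 18 rose and 1 fell (13 and 1 adjusted over the list alone, median 3.39). Il6 was at least 20-fold higher and Il18 rose 7.05-fold. Of the chemokine genes 9 of 18 rose (9 adjusted over the list alone, median 2.39), among them Ccl3, 10.2-fold, and Ccl4, 4.15-fold. Inflammatory effector genes had 15 rises and 1 fall among 25 (17 and 2 adjusted over the list alone, median 3.11), including the glutamate and cystine exchanger gene Slc7a11 (26.7-fold) and the iron-sequestering lipocalin gene Lcn2 (at least 11.9-fold). The camera adjusted p of these 3 lists was 4.52e-10, 3.94e-08 and 2.29e-11, and each had an adjusted p = 0.0928 with an estimated correlation. With undetected members set to their bounds, the medians of the interferon, cytokine and effector lists were 2.75, 2.88 and 2.93. Within replicates 1 and 2 the medians were 2.85 and 4.09 for cytokines, 2.37 and 2.53 for chemokines and 2.09 and 3.37 for effectors. Untreated replicate 2 minus replicate 1 had medians of -0.086, -0.607 and -0.614 over these 3 lists.

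Costimulation and antigen presentation genes had 10 rises among 21 (12 adjusted over the list alone, median 1.14), with Cd40, a costimulatory receptor, 49.3-fold higher (log2 change 5.62, and from 3.18 to 5.96 over 3 other probes) and the peptide transporter gene Tap1 7.72-fold higher. Its camera adjusted p was 2.58e-08, and the adjusted p = 0.187 with an estimated correlation. Survival and death genes had 9 rises among 17 (10 adjusted over the list alone, median 1.44, and 0.94 and 2.21 within replicates 1 and 2), including Traf1 (31.3-fold) and Birc2 (4.37-fold). Other negative regulators of TLR signalling had 7 rises among 18 (10 adjusted over the list alone, median 2.64, or 2.43 with undetected members at their bounds), with Socs1 at least 4.15-fold and Dusp2 25.4-fold higher. The TLR4 receptor and proximal signalling list had 5 rises and 1 fall among 20 (9 and 1 adjusted over the list alone, median 0.64), led by Irak2 at 7.75-fold. The IRF, STAT and C/EBP list had 7 rises and 1 fall among 15 (12 and 1 adjusted over the list alone, median 0.95), with Batf2 rising 32.1-fold and Cebpa falling by at least 1.49-fold. These 4 lists had camera adjusted p values from 3.94e-08 to 0.000348, and each had an adjusted p = 0.0928 with an estimated correlation. Adjusted over the list alone, 4 NF-kB subunit genes and 5 IkB genes rose. The NF-kB subunit and IkB lists had camera adjusted p values of 0.000557 and 6.95e-05, with an adjusted p = 0.0928 and an adjusted p = 0.187 with an estimated correlation.

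Camera called the cell cycle and cholesterol synthesis lists downward. Among 29 cell cycle genes 11 fell and none rose (14 adjusted over the list alone, median log2 change -0.997). Ccnd1, encoding cyclin D1, fell 4.79-fold (-2.26 ± 0.28, adjusted p = 0.0119), and Ccne2 and Cdc6 fell to below detection, by at least 3.15-fold and 2.73-fold. Its camera adjusted p was 8.14e-06, and the adjusted p = 0.205 with an estimated correlation. Among 18 cholesterol synthesis genes 5 fell (6 adjusted over the list alone, median -0.67), including Stard4, 6.11-fold, and Msmo1, 3.7-fold. Its camera adjusted p was 0.0153, and the adjusted p = 0.503 with an estimated correlation. Fry called the cell cycle list (adjusted p = 0.00951) but not the cholesterol synthesis list (0.0886). The immediate-early list (median 0.64), macrophage surface receptors (0.32), glycolysis (0.12), LXR targets (-0.00), heat shock and amino acid stress genes (-0.06), ribosomal proteins (-0.21), lysosome genes (-0.22) and the TCA cycle and respiratory chain (-0.27) were not called by camera, with adjusted p values from 0.143 to 0.832. The TCA cycle, lysosome and ribosomal lists were called downward by fry, which tests a list without comparing it with other genes (adjusted p = 0.0088, 0.00599 and 0.0192). For the LXR and heat shock lists camera's direction was upward while the median and mean were negative. The median log2 change of all genes tested was -0.18, and -0.61 with median scaling, so list medians are read against it.

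In all, 499 genes rose and 647 fell at high LPS by limma. With the replicate number as a block the counts were 1156 and 1949, and with the slide as a block they were 975 and 1452. All 1146 genes called without a block were also called with the replicate block and had the same sign in both replicates. With the slide block 1141 of them were called. High-LPS replicate 2 was alone on its slide, so the slide-block estimates rest on high-LPS replicate 1 and take in no spread between high-LPS arrays. Rises were 43.5% of the calls, against 17.1% with median scaling (361 and 1745), 54.5% with cyclic loess (547 and 456) and 56% when scaled on the probes detected on all arrays (576 and 452). Leaving out untreated replicate 1 or 2 left 49 rises and 12 falls or 19 and 8, and leaving out high-LPS replicate 1 or 2 left 108 and 63 or 10 and 2.

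The comparison of low LPS with no LPS asked what a dose of 0.1 ng/ml changed. With the slide as a block, 42 genes rose and 4 fell, and without a block limma called 0 genes in either direction (220 of 7767 had an unadjusted p under 0.05, and the lowest adjusted p was 0.255). Because of that, the genes named next were chosen from the slide-block fit after the data were seen. That fit has 1 residual degree of freedom. In 100 simulations with all groups unchanged, a mean of 4.66 genes (0 to 14) still passed in it at low and at high LPS alike. Simulated calls at low LPS alone were not recorded and can only be as many or more. Its adjusted p values may therefore be too small. Socs3, a suppressor of cytokine signalling, was 64.4-fold higher at low LPS (log2 change 6.01 ± 0.81 SE in the fit without a block, n = 2 arrays per group). Its limma adjusted p was 0.022 in the slide-block fit and 0.393 without a block. Its log2 change was 4.73 within replicate 1 and 7.29 within replicate 2, and 7.30 or 4.71 without low-LPS replicate 1 or 2. For Cd69, Cd40, Icam1 and Nfkbie the changes within replicates 1 and 2 were 3.25 and 4.39, 2.03 and 3.59, 1.83 and 3.20, and 1.97 and 3.03. The early activation marker gene Cd69 was 14.1-fold higher (0.0178 and 0.255 in the same 2 fits) and the signalling adaptor gene Traf1 was 9.8-fold higher (0.0178 and 0.393). Cd40, Hcar2, Tnfaip2, Icam1, Nfkbie and Slc7a11 were between 5.45-fold and 7.02-fold higher, Cdc42ep2 was 9.32-fold higher, Nlrp3, detected on 1 of 2 untreated arrays, was at least 5.19-fold higher, and Edn1, undetected without LPS, was at least 3.16-fold higher. The 4 falls in that fit were Dusp6, a MAP kinase phosphatase gene (2.94-fold), Cnr2 (2.58-fold), Lpar6 (2.29-fold) and Cdk20 (2.17-fold).

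IkB genes had the largest median among the lists at low LPS, 2.20, and all 6 members had positive changes. None passed the test over all genes and 5 passed when adjusted over the list alone. Nfkbia had a log2 change of 3.001 ± 0.52 (adjusted p = 0.623; 1.90 and 4.10 within replicates 1 and 2), Nfkbiz of 4.97 ± 1.09 (0.791; 2.52 and 7.42), Nfkbie of 2.50 ± 0.46 (0.623, and 0.027 with the slide block) and Bcl3 of 1.48 ± 0.46 (1.00, and 0.0196 with the slide block). The IkB list had a camera adjusted p of 1.39e-13, and the adjusted p = 0.0782 with an estimated correlation. The 4 NF-kB subunit genes had a median of 1.16 (camera adjusted p = 1.01e-06, and an adjusted p = 0.0782 with an estimated correlation), with Rela at 0.61 ± 0.17. Rel, detected on 1 of 2 untreated arrays, was at 1.13 ± 0.49, a fitted change taken partly against background. Tnfaip3 was at 3.48 ± 0.94, Ikzf1 at 0.27 ± 0.22 and Ikzf5 at 0.16 ± 0.22, none of them called with or without a block. Other negative regulators of TLR signalling (median 1.16), cytokines (1.09), survival and death genes (1.05), immediate-early genes (0.73), chemokines (0.60) and inflammatory effectors (0.56) were also called upward by camera, with adjusted p values from 1.95e-13 to 2.66e-07. Low-LPS replicate 2 stood apart in most of them: within replicates 1 and 2 the medians were 0.68 and 1.42 for other negative regulators, 0.38 and 1.76 for cytokines and 0.64 and 1.19 for survival genes. They were 0.28 and 1.35 for chemokines, 0.37 and 0.89 for immediate-early genes and 0.71 and 0.58 for effectors. With an estimated correlation their adjusted p lay between 0.0782 (other negative regulators, survival and chemokine lists) and 0.218 (immediate-early list). Adjusted over the list alone, 5 other negative regulators, 3 cytokine, 4 survival, 6 chemokine and 2 effector genes rose, and 0 immediate-early genes. With undetected members at their bounds the medians of the other negative regulators, cytokines and effectors were 1.06, 0.71 and 0.54. Among their members, Ccl4 was 3.7-fold, Ccl3 5.4-fold, Clec4e 5.31-fold and Tnfrsf1b 3.08-fold higher, each with an adjusted p of 0.0178 in the slide-block fit.

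The interferon-stimulated list was called upward at low LPS with a median of 0.12 and no member passing, even when adjusted over the list alone. Its camera adjusted p was 0.00688, and the adjusted p = 0.713 with an estimated correlation. The median was 0.17 within replicate 1 and 0.04 within replicate 2. Camera kept the upward call with the replicate block (adjusted p = 0.00822) and the slide block (0.00031). In fits without a block the median was -0.32 without untreated replicate 2 and -0.38 without low-LPS replicate 1. Over this list untreated replicate 2 minus untreated replicate 1 had a median of -1.01, so those fits take in a replicate difference. The direction thus depended on keeping the replicate numbers balanced. Costimulation genes (0.24), the IRF, STAT and C/EBP list (0.09), the TLR4 list (0.15) and heat shock and amino acid stress genes (0.02) were called upward and cell cycle genes (-0.14) downward. With an estimated correlation none of these was called, with adjusted p values of 0.278, 0.203, 0.114, 0.218 and 0.327 in that order. Heat shock genes lost the call with the replicate block (adjusted p = 0.0663). The cell cycle median was -0.29 and -0.14 within replicates 1 and 2, and 0.025 in the fit without a block and without low-LPS replicate 1. The other 7 tested lists had medians between -0.21 (macrophage surface receptors) and -0.00 (glycolysis) and camera adjusted p values of 0.0853 or more, with the glycolysis mean and camera direction upward.

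With the replicate block limma called 0 genes at low LPS and 565 had an unadjusted p under 0.05, with replicate as a random effect 5 genes were called higher, and without low-LPS replicate 1 the fit without a block called 4. The slide-block fit rests on 1 residual degree of freedom. Changes of at least 1 on the log2 scale in the same direction within both slides were seen for 75 genes upward and 4 downward.

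**Figure D2:**
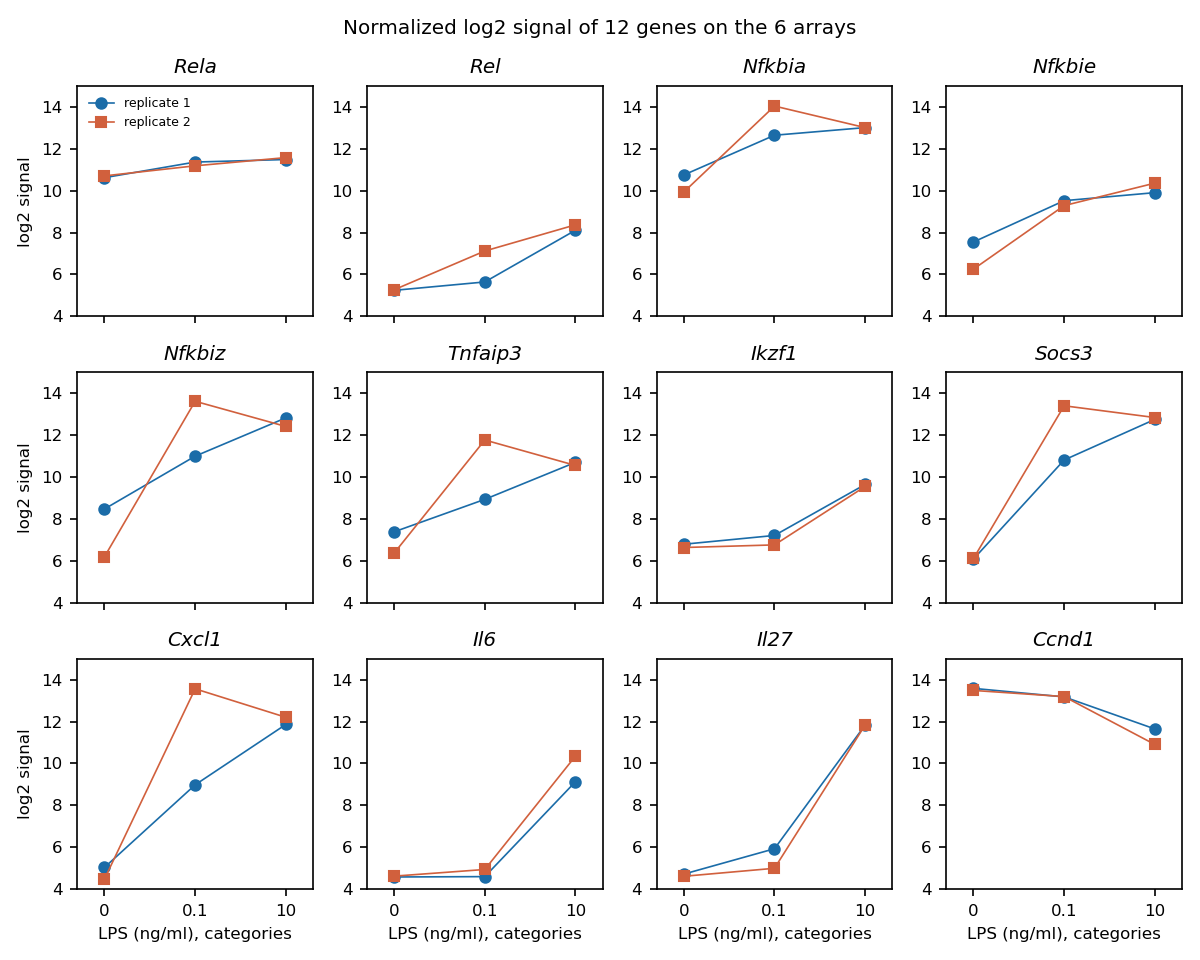
Normalized log2 signal (vertical axis) of 12 genes against the LPS dose as 3 categories (horizontal axis, ng/ml), 1 panel per gene, with circles for replicate 1, squares for replicate 2 and lines joining arrays of the same replicate number. Nfkbiz, Tnfaip3, Socs3 and Cxcl1 in low-LPS replicate 2 lie above both high-LPS arrays, with Nfkbiz at 13.6 against 12.8 and 12.4, while Il27 and Ikzf1 are high on the high-LPS arrays alone.

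The comparison of high with low LPS tested directly which genes differed between the doses. Il27, detected on 1 of 2 low-LPS arrays, was at least 78.6-fold higher at 10 ng/ml than at 0.1 ng/ml (fitted log2 difference 6.37 ± 0.33 SE, n = 2 arrays per group, limma adjusted p = 0.00994). Cxcl9, Hdc and the interferon-stimulated gene Mx1, also detected on 1 of 2 low-LPS arrays, were at least 64.7-fold, 55-fold and 30.4-fold higher. Edn1 was 32.5-fold, Gbp5 28.7-fold, Calhm6 26.6-fold and Batf2 25.1-fold higher. Il6 and Nos2, which encodes the inducible nitric oxide synthase, were undetected at low LPS and at least 20.5-fold and 16.9-fold higher at high LPS. Ikzf1 was 6.12-fold higher (2.61 ± 0.22, adjusted p = 0.0122), and none of the NF-kB subunit and IkB genes differed between the doses without a block. With the replicate block Rel (limma adjusted p = 0.0274, against 0.0909) and Nfkb2 (0.0345, against 0.142) were called as well. In the fit without a block their log2 differences were 1.86 ± 0.49 and 1.65 ± 0.55.

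Lower at high than at low LPS were Sesn1 (at least 17.2-fold, detected on 1 of 2 high-LPS arrays), Zfp36l1 (12.2-fold), Tmem86a (8.49-fold) and Lhfpl2 (8.46-fold). Cdca7, Fam78a, Gpr183, Mbp, Jade1 and Rab3il1 were undetected at high LPS and lower by at least 12.8-fold, 6.66-fold, 5.56-fold, 6.1-fold, 5.41-fold and 4.15-fold. For Mbp the 2 other probes had log2 changes of -0.50 and -0.28 at high LPS against none, where the tested probe had -3.61, so this fall rests on 1 of 3 probes. For Nfkbia the log2 difference was -0.33 ± 0.52 (adjusted p = 0.738), for Nfkbiz 0.31 ± 1.09 (0.894), for Tnfaip3 0.28 ± 0.94 (0.892) and for Rela 0.26 ± 0.17 (0.411). The sign turned without low-LPS replicate 2 for Nfkbia (0.36) and without low-LPS replicate 1 for Nfkbiz (-0.998) and Tnfaip3 (-1.14).

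Interferon-stimulated genes had 17 members higher at high than at low LPS and 36 of 36 when adjusted over the list alone, with a median of 2.998, a camera adjusted p of 4.37e-25 and an adjusted p = 0.21 with an estimated correlation. Inflammatory effectors had 9 of 25 higher (14 higher and 1 lower adjusted over the list alone, median 2.02, Upp1 19.4-fold) and cytokines 7 of 18 higher and 1 lower (8 and 1 adjusted over the list alone, median 2.58, Il18 7.63-fold), each with an adjusted p = 0.2 with an estimated correlation. Chemokines had 3 of 18 higher (Ccl5 21-fold, Ccl12 6.7-fold), costimulation genes 5 of 21 (Tap1 7.56-fold), the IRF, STAT and C/EBP list 3 of 15 (Batf 5.98-fold) and survival and death genes 3 of 17 (Bcl2a1d 5.79-fold). Adjusted over the list alone these counts were 3, 10, 8 (with 1 lower) and 9. Their camera adjusted p values lay between 3.71e-07 and 0.000273, and between an adjusted p = 0.2 and an adjusted p = 0.21 with an estimated correlation. Other negative regulators (1 of 18 higher, Socs1, at least 4.24-fold), the TLR4 list (1 of 20, Irak2, 2.86-fold) and NF-kB subunits (0 of 4, median 1.19) were called at 0.000694, 0.00146 and 0.0201, with 1, 3 and 1 members higher adjusted over the list alone. Their adjusted p = 0.2, 0.2 and 0.21 with an estimated correlation, and the NF-kB list lost the call with the slide block (adjusted p = 0.0633). Cell cycle genes (6 of 29 lower, 13 adjusted over the list alone, Ccnd1 3.75-fold, median -0.92) and cholesterol synthesis genes (2 of 18 lower, 6 adjusted over the list alone, Stard4 5.56-fold, median -0.68) were called downward at 1.91e-05 and 0.00963, with an adjusted p = 0.21 and an adjusted p = 0.548 with an estimated correlation. Fry did not call the cholesterol synthesis list (adjusted p = 0.116) or the costimulation list (0.0515). The IkB list (median 0.52, camera adjusted p = 0.291) and the immediate-early list (-0.40, 0.749) were not called. Within replicates 1 and 2 their medians had opposite signs, 0.37 and -0.34 for IkB and 0.20 and -0.90 for immediate-early genes. The medians were also smaller in replicate 2 for chemokines (2.02 and 0.56) and other negative regulators (1.21 and 0.27), but larger for interferon-stimulated genes (2.21 and 3.43). The median over all genes was -0.14. For LXR targets camera's direction was upward with a negative median (-0.03).

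Over all genes 239 were higher and 232 lower at high than at low LPS by limma. The counts were 827 and 1315 with the replicate block and 661 and 858 with the slide block. Both block fits called all 471 genes, but the slide-block estimates rest on high-LPS replicate 1 alone. Higher genes were 50.7% of the calls, against 22.8% with median scaling, 61.2% with cyclic loess and 62.7% when scaled on the probes detected on all arrays. The untreated arrays enter this comparison only through the spread, and with the 2 dose groups alone 23 genes were higher and 8 lower. Without untreated replicate 1 or 2 the counts were 23 and 8, without low-LPS replicate 1 or 2 they were 87 and 46 or 11 and 1, and without either high-LPS array they were 0 and 0.

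**Figure D3:**
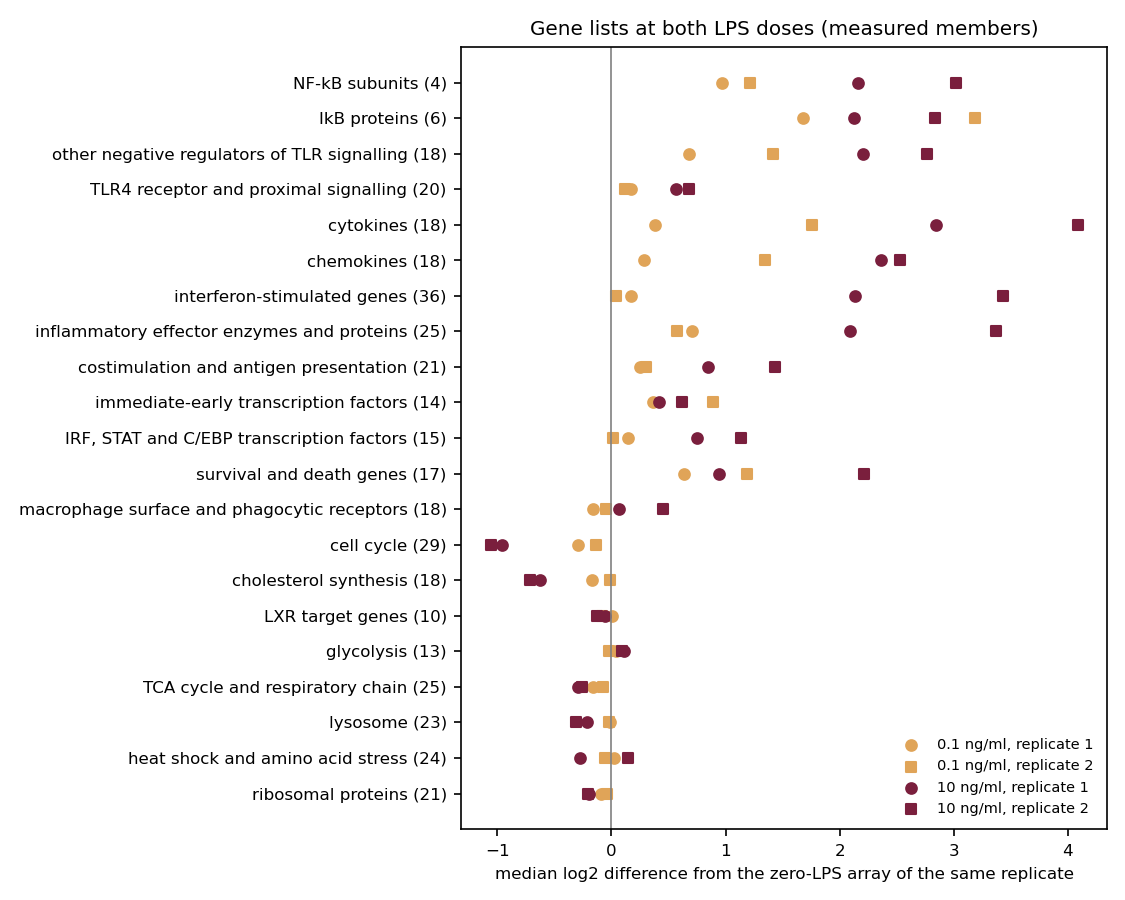
Median log2 difference (horizontal axis) between each LPS-treated array and the untreated array of the same replicate number, over the measured members of the 21 tested gene lists (1 line each, number of members in brackets), with colour for the dose and shape for the replicate. For interferon-stimulated genes the low-LPS medians are 0.17 and 0.04 and the high-LPS medians 2.13 and 3.44, and for IkB proteins they are 1.68 and 3.19 against 2.13 and 2.84.

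To set the doses side by side, the low-LPS change was expressed as a percentage of the high-LPS change for genes called at high LPS. Among the 499 genes that rose the median was 16.4% (quartiles 3.25% and 34.9%), with 64 genes at 50% or more and 199 under 10%. The 5 IkB genes that rose had a median of 77.5%, the 7 other negative regulators 71.8%, the 9 chemokine genes 62.7% and the 3 NF-kB subunits 41.9%. The 26 interferon-stimulated genes had a median of 5.4%, the 10 cytokine genes 7.77% and the 15 inflammatory effector genes 13.2%. Since both changes share the untreated arrays, 100 simulations with low LPS unchanged and the high-LPS effects kept, added after the shares were seen, gave a simulated range without a low-LPS change. It was -1% to 3.29% for all rises, -24.9% to 24.1% for IkB, -17.2% to 11.8% for other negative regulators, -12.3% to 11.3% for chemokine, -56.7% to 21.1% for NF-kB and -6.07% to 6.47% for effector genes. The interferon and cytokine shares lay within their ranges, -10% to 7.69% and -8.89% to 9.3%, though within replicates 1 and 2 they were 11.3% and 1.04%, and 15.2% and 5.42%. Within replicates 1 and 2 the shares were 21.3% and 9.94% for all rises, 82.1% and 86.6% for IkB, 46.6% and 83.7% for other negative regulators, 47.2% and 87.7% for chemokine and 65.5% and 55.1% for NF-kB genes. Single genes varied more than the NF-kB medians, which came from different genes. Nfkb2 had low and high changes of 1.798 and 2.745 in replicate 1, and 0.586 and 2.945 in replicate 2. For Rel they were 0.401 and 2.871, and 1.85 and 3.1. Among the 647 genes that fell the median was 20.3%, against a simulated range of 0.0358% to 3.95%. These shares have no test, since genes are not replicates. The simulated ranges are too narrow where the genes of a list shift together on an array. Camera's estimated correlation ran from -0.156 (NF-kB subunits) to 0.786 (interferon-stimulated genes), with 0.389 for the IkB list. With 1 array left out, the median was taken over the genes called in that fit, which were fewer, so it is not the same genes that are compared. For the rises it was 30.7% or 31.7% without untreated replicate 1 or 2, 8% or 25.9% without low-LPS replicate 1 or 2 and 8.34% or 8.85% without high-LPS replicate 1 or 2. For the falls it was 13.2% without low-LPS replicate 1.

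Without a block no gene was called at both doses. With the slide block, where the high-LPS change rests on replicate 1, 41 genes rose and 4 fell at both. Independent lists would share 5.27 and 0.748, but both comparisons use the same untreated arrays. In 100 simulations with low LPS unchanged, the high-LPS effects kept and as many genes of smallest p taken at low LPS, 19.1 rises (10 to 28) and 1.26 falls (0 to 4) were shared. With all groups unchanged, 4.66 calls (0 to 14) were shared with the slide block. The simulation with high-LPS effects kept was added after the overlap was seen. The fold changes at the 2 doses correlated across genes with r = 0.654, against 0.494 (0.428 to 0.552) in 100 simulations of unchanged groups sharing the untreated arrays, with noise drawn independently for each gene. Their covariance was 0.263 against 0.103, a difference of 0.16. The simulated noise was also independent between arrays and of a size that includes the replicate difference, which the groups share in the data. The value of 0.103 may therefore be too large, so 0.16 does not measure the excess. With 2 untreated arrays the controls could not be divided between the doses, and genes are not independent replicates.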

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

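The search for genes with opposite changes at the 2 doses, its size minimum of 0.5 log2 and the test of scaling on the probes detected on all arrays were chosen after the result was seen, while the contrast of the doses, the replicate block and median scaling were planned. For 4 genes the fitted changes at low and high LPS had opposite signs and the doses differed by limma. Hhex, encoding a homeobox transcription factor, had a log2 difference between high and low LPS of 2.15 ± 0.25 (adjusted p = 0.0214), from -0.82 at low and 1.34 at high LPS against none. Myc, a transcription factor gene linked to growth, was undetected on both high-LPS arrays and at least 1.56-fold lower at high than at low LPS (0.0181). Its fitted difference of -1.96 ± 0.20, from 0.82 and -1.14, rests on background. Its untreated signals of 5.89 and 5.76 lay near or below the high-LPS detection floors of 6.13 and 5.88, so no fall at high LPS against none is shown. P2ry14, encoding a nucleotide-sugar receptor, had a difference of 1.98 ± 0.32 (0.0339), from -0.54 and 1.44. Sertad3 had a difference of 3.17 ± 0.59 (0.0464), from -0.62 and 2.56, and its low-LPS change was 0.13 in replicate 1 and -1.36 in replicate 2. None of the 4 was called at low LPS (adjusted p = 1.00 each), so the opposite direction there was not shown, while at high LPS their adjusted p values were 0.0297, 0.0251, 0.0438 and 0.0468. With the replicate block the difference between the doses had adjusted p values of 0.00821, 0.00691, 0.00921 and 0.017.

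Under median scaling the calls at high LPS were mostly falls, with rises making up 17.1% of the calls against 43.5% with quantile normalization. If undetected probes, on which the array medians rest, had set this split, scaling on the probes detected on all 6 arrays was to bring the share back to within 10 points. It gave 56%, which is above the quantile value by more than that, a result the written prediction did not cover. The choice of probes to scale on therefore moved the split past the quantile value, and which split is closest to the RNA content of the cells stays open. No biological explanation was tested.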

How the results depend on the processing

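Scaling on the probes detected on all arrays, the fit behind the low-LPS gene names and the tests of single arrays in the last part were chosen after the result was seen, and the other settings before. Over 285 results and 29 settings, 6553 of 7399 values stayed the same, 639 were weaker, 132 stronger, 61 moved and 14 reversed. For genes and called lists, the same meant an unchanged direction and side of the threshold, including genes uncalled in both fits. Lists uncalled in the main fit were compared by side of the threshold alone, and gene values on replicate 1 alone by direction alone. Counts and shares stayed the same if within a set factor of the main value. The list tests did not use the fold or stricter thresholds, the variance trend, the array weights or the random replicate effect. List values under those settings were therefore the same by construction. Median scaling gave 1 gene higher at low LPS, 1745 lower at high LPS, 701 lower at high than at low LPS and 1 call shared by the doses. Requiring detection on all 6 arrays gave 152 lower between the doses, where fewer genes were tested. At an adjusted p under 0.01, the calls were 70 and 33 at high LPS and 4 and 1 between the doses, by the stricter threshold. With only the 2 groups compared in the fit, 23 and 8 were called between the doses, from fewer arrays. The replicate block gave 1156 and 1949 at high LPS and 827 and 1315 between the doses. The slide block gave 42 and 4 at low LPS, 975 and 1452 at high LPS, 661 and 858 between the doses and 45 shared. Its high-LPS estimates rest on high-LPS replicate 1. A random replicate effect gave 5 higher at low LPS, 1108 and 1818 at high LPS, 814 and 1248 between the doses and 5 shared. An estimated correlation left 0, 0 and 0 lists called by camera at low LPS, at high LPS and between the doses (lowest adjusted p 0.0782, 0.0928 and 0.2). The TLR4 list (estimate 0.00139) and the NF-kB subunit list (-0.156) lost their calls too. Their estimates lie below the preset 0.01, so correlation among members does not by itself account for the loss. Fry called 0, 15 and 12 lists in the same order (lowest adjusted p 0.0794, 0.00599 and 0.0314). Leaving out 1 array gave 10 to 470 rises and 2 to 492 falls at high LPS, 0 to 87 and 0 to 46 between the doses, 0 to 4 rises and 0 falls at low LPS and 0 to 4 shared calls, with the lone array assumed to vary like the others. The number of lists called ranged from 10 to 14, 12 to 14 and 10 to 13. The low share of the high change ranged from 8% to 31.7% for rises and 13.2% to 25.3% for falls, each over the genes called in that fit. The direction turned with median scaling for Ikzf5 (-0.22 at high LPS, -0.30 between the doses) and Tnfaip3 (-0.003 between the doses), and with scaling on detected probes for Nfkbia (0.21 between the doses). Leaving out 1 array, log2 values ranged from -0.087 (without untreated replicate 1) to 0.396 for Ikzf5 at low LPS, from -0.38 (without low-LPS replicate 1; -0.32 without untreated replicate 2) to 0.738 for the interferon list at low LPS and from -0.44 to 0.025 (without low-LPS replicate 1) for the cell cycle list. Between the doses they ranged from -0.998 and -1.14 (without low-LPS replicate 1) to 1.62 and 1.69 for Nfkbiz and Tnfaip3, and from -1.03 and -1.82 to 0.36 and 0.59 (without low-LPS replicate 2) for Nfkbia and Nfkbid. The fits with 1 array left out had no block, so they also take in differences between the replicate numbers. On replicate 1 alone Nfkbia (0.36) and Nfkbid (0.36) turned as well. For the changes whose construction does not show it, the cause was not tested. Genes near the background on an array have compressed changes.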

Other observations

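The test across other probes of the same genes was planned before its result was seen, and the other tests in this part were chosen after the result was seen. The next genes were picked after their values were seen, from those whose change from the untreated array differed most between the low-LPS replicates. Egr1, encoding an immediate-early transcription factor, had log2 signals of 6.28 and 11.6 in low-LPS replicates 1 and 2, against 8.37 and 8.89 on the high-LPS arrays. Egr2 had 7.51 and 11.2 against 6.99 and 6.996, and Tnfsf9, a ligand gene of the TNF family, 6.86 and 13.2 against 7.30 and 7.51. Ifnb1, encoding interferon beta, had 4.90 and 9.35 against 10.0 and 10.0, and the growth factor gene Csf2 had 4.46 and 8.45 against 6.17 and 7.27, both below the detection floor in low-LPS replicate 1. The median change over the cytokine list at low LPS was 0.38 in replicate 1 and 1.76 in replicate 2, and over the interferon-stimulated list 0.17 and 0.04.

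Immediate-early genes were higher in low-LPS replicate 2 than in replicate 1, by a median of 0.95 over 14 members. A general offset between slides or experiments was argued against by the untreated arrays, where that median was -0.03, and normalization by a lowest difference of 0.702 between the low and untreated offsets over 5 other normalizations. More LPS in replicate 2 stays open: the low-LPS change was not larger there over the interferon list (median -0.153, quartiles -0.412 and 0.0685), but was larger by at least 0.3 log2 over 5 of the 10 lists called higher at high than at low LPS, among them cytokines (1.17) and chemokines (0.53). Over 3 of the 10 lists, the interferon list included, the median was below 0. In 11 of the 14 members low-LPS replicate 2 lay above both high-LPS arrays, against 6 for replicate 1, but members lower at high LPS than without it pass this count by themselves and the rest largely restates the pattern. An earlier stage of the response in that sample therefore stays open, as does a difference in its handling, which was not tested.

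Replicate numbers separated the arrays in all 3 groups, with 1343 genes called in a limma fit with group and replicate terms. Only 1 of the 4 ways to pair the arrays gave as many, the highest other being 0, and 4 pairings are too few for a share under 0.05. An effect of slides on single probes was argued against by 413 other probes of the same genes, whose replicate differences correlated with those tested with r = 0.926 (96.1% with the same sign). The replicate differences correlated with at least 0.634 between groups whose replicate 2 lay on different slides, which the written prediction took to exclude a slide offset, but both slides may differ from slide 1 alike, so slide and preparation cannot be told apart here, and no biological explanation was tested. Cells of another type stay open, since at most 1 marker of any list was detected on all 3 arrays of 1 replicate number and on none of the other, while only 37 of 82 markers had a named probe.

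Among the 9 measured markers of other cell types, limma without a block called 0 between the LPS groups, and the fit with a replicate term called 8 by replicate number. With the replicate block 2 were called at high LPS, the T cell marker Cd28 (log2 change -2.03, adjusted p = 0.00854) and the neutrophil marker Mmp9 (0.91, 0.048), and Cd28 also between the doses (-1.26, 0.0358). With the slide block Cd28 (0.00745) and the T cell marker Cd3e (0.0224) were called at high LPS. Of the 37 named, 4 were detected on all arrays and 28 on none. Another 2, the T cell marker Cd3e and the neutrophil marker Mmp9, were detected on all replicate 1 arrays and no replicate 2 array. The fitted changes of Cd3e and Mmp9 at high LPS are therefore taken partly against background. The B cell, NK cell, erythroid, stromal, dendritic, mast cell and megakaryocyte lists each had 0 by that criterion, though the B cell markers Cd22 (replicate 1) and Cd79b (replicate 2) and the NK cell marker Prf1 (replicate 2) were each detected on the untreated and low-LPS array of 1 replicate number alone. The neutrophil gene S100a8 had log2 signals of 7.75 and 5.77 without LPS, 7.21 and 5.81 at low LPS and 7.69 and 6.39 at high LPS. By camera on the replicate term, interferon-stimulated (adjusted p = 6.16e-05, median -0.71) and costimulation genes (0.0428, -0.44) were lower in replicate 2, and cell cycle (0.0116, 0.32) and cholesterol synthesis genes (0.0106, 0.35) higher. Each of the 4 had an adjusted p = 0.954 with an estimated correlation.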
